A study of Danio rerio with 26 samples.

How the data were processed

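RNA was measured by sequencing in 26 zebrafish libraries, which fall into 3 tables. The oocyte table holds stages I, II, III and IV (2 libraries each). The embryo table holds wild-type embryos at 0, 2, 4 and 6 hours post fertilisation (hpf, 3 libraries each). The knockdown table holds 4 hpf embryos labelled znf281b KD and pCas13d alone (3 libraries each). Groups and replicate numbers were taken from the sample titles, and every column of the tables matched 1 sample.

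The authors deposited TPM per gene, a unit scaled within each library to a total of 1000000, so a value is a share of the library and not an amount per cell. Reads were aligned with STAR 2.7.3a and quantified with RSEM on danRer11, per the submitters' processing notes. The gene annotation release and any trimming or filtering steps are not given in the sources used here. Per the labels' protocols, oocyte and embryo libraries were ribosomal-RNA-depleted stranded total RNA libraries, from 100 ng of oocyte RNA or 500 ng of embryo RNA, sequenced as single reads. Each oocyte library came from 50 oocytes and each embryo library from 20 embryos, per the series' design text. By that text, stages I and II were collected 1 to 2, stage III 4 to 7 and stage IV 8 to 10 days after mature eggs had been purged by mating. Isolation differed by stage: stages I and II with a pair of collagenases, stage III with one of them, and stage IV mechanically with none. The knockdown libraries were run on another sequencer (G4), per the labels. Their library kit, RNA input, guide RNAs and number of embryos are not given in the sources used here.

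The 3 tables list the same 32520 gene identifiers, of which 76 have no name and 1311 share a symbol with another identifier. Genes were joined by identifier and named as in the embryo table, because names differed for 3757 genes in the oocyte table and 19 in the knockdown table, and 17 and 18 names there had been turned into dates. The reference gene names used here, from an annotation of assembly GRCz12tu, held 29201 of the identifiers. No coordinates are given, since that assembly is not the authors' build. Genes with the same symbol, the copies of dre-mir-430, MFAP4 and hbba1, and the numbered zinc finger genes are named as copies of 1 gene or family, between which reads can be split. Their sequences were not compared here, so their single values are taken as uncertain. No columns belonged to samples outside the series (0 columns). TPM keeps no read depth, so the depth of each library is unknown, no counting interval is given, and genes with low TPM are the least precise.

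Tests used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 fit per table over all its groups and empirical Bayes moderation with a mean trend. Genes with a TPM of at least 1 in at least 3 libraries (2 for oocytes) were tested. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, a gene was called at an adjusted p under 0.05, and summary counts of embryo and oocyte comparisons also needed a change of at least 2-fold. For the knockdown the summary count has no fold minimum. All fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM. Tests were made only within a table, because the tables were normalised separately. For znf281b and znf281a in the knockdown, a two-sided exact permutation test of the 3 libraries against 3 was added.

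The 24 gene lists cover pluripotency and genome activation factors, early zygotic dorsoventral and mesendoderm regulators, BMP and ventral factors, dorsal organizer factors, enveloping layer and epithelial genes, oocyte-specific and maternal-effect genes, germ plasm and piRNA pathway, meiosis, and RNA storage, deadenylation and decay. They further cover cell cycle and checkpoint, zona pellucida, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, proteasome subunits, the NuRD complex, p53 response, interferon and antiviral response, heat shock and unfolded protein response, and the numbered zinc finger family. The last 4 are ovarian follicle somatic cell markers, stromal and vascular wall markers, blood, endothelial and immune markers, and vitellogenins. Lists with at least 5 tested members were compared with the other genes by limma's camera with a preset correlation of 0.01, and again with a correlation estimated from the data. Members called were counted over all genes tested and adjusted over the list alone. Sets of genes called with at least 2-fold change between embryo stages were tested in the knockdown and oocyte fits in the same way.

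The groups, the tests of genes and lists, the lists, the rule for named genes and all alternatives except 3 were chosen before the data were examined. Part of the tests under Other observations were chosen afterwards, as stated there. The rule names, per comparison, the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 TPM in the higher group, groups that do not overlap and a symbol that is not a clone name. It adds up to 4 called members per list, and always znf281b, znf281a, nanog, pou5f3, sox19b, tbxta, sox32, gsc, chrd, bmp2b, vox, buc, zar1, dazl, ddx4 and gdf9. The text gives a part of the genes so named. The 3 alternatives chosen after seeing the data left S6 kinases out of the ribosomal protein list, named the largest changes with the copies of dre-mir-430 left out, and used the replicate number as a block in a fit of only 4 and 6 hpf. For 4 against 6 hpf the libraries were taken as paired by replicate number, from the data and not from the labels: deviations from the group means correlated at 0.32, 0.127 and 0.181 for numbers 1, 2 and 3.

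The alternatives planned were a pseudocount of 0.1 TPM, no filter on low values, a stricter filter of 5 TPM, median-of-ratios scaling, quantile normalisation, rescaling without mitochondrially encoded genes, the replicate number as a block, a fit of only the 2 groups compared, leaving out each library in turn, and camera with an estimated correlation. Median-of-ratios scaling divides each library by the median of its ratios to the geometric mean over genes above 1 TPM in all libraries of the table. The rescaling without mitochondrially encoded genes took out only genes whose symbol starts with mt-, so any listed under another name were kept.

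The gene test was tested on simulated data in which 100 genes were changed by 1 and 100 by 2 on the log2 scale. With the embryo design it called 79, 83, 84 and 83 of the genes changed by 1 and 100, 97, 98 and 96 of those changed by 2, for 2 against 0, 4 against 2, 6 against 4 and 6 against 0 hpf (16328 genes each). With the oocyte design it called 17, 21, 16 and 12 of those changed by 1 and 59, 58, 67 and 51 of those changed by 2, for stage II against I, III against II, IV against III and IV against I (16067 genes each). With the knockdown design it called 53 and 89 (15068 genes). Unchanged genes made up at most 5.96% of the calls, in the knockdown design. Few genes were changed and noise was independent between genes, unlike in the data. These numbers are therefore not the power of the tests made here. Figures were drawn with matplotlib 3.10.9.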

Results

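Transcripts were measured across zebrafish oocyte growth, across the first 6 hours of embryonic development, and in embryos in which znf281b, a gene encoding a zinc finger protein, was knocked down. The oocyte libraries covered stages I to IV (n = 2 libraries per stage), the embryo libraries 0, 2, 4 and 6 hpf (n = 3 per time), and the knockdown libraries 4 hpf embryos labelled znf281b KD or pCas13d alone (n = 3 each). Cas13d is an RNA-guided nuclease that cuts RNA. Values are TPM as mean ± SD over those libraries, and log2 changes are given with their SE from limma. The oocyte and embryo libraries are described as biological replicates of pooled oocytes or embryos, while nothing is said of the origin of the knockdown replicates. P-values therefore measure only the spread between these samples, which may be technical in the knockdown. Depth is unknown because TPM keeps none. Libraries of 1 group correlated across genes with Pearson's r of at least 0.973 (embryos), 0.971 (knockdown) and 0.961 (oocytes) on log2(TPM + 1), where genes are not independent replicates, and 0 pairs of libraries were identical.

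Between 0 and 2 hpf, before most zygotic genes are switched on, the transcript population of the embryo stayed close to that of the egg. MZT1, which encodes a protein of the microtubule-nucleating gamma-tubulin complex, dropped from 45.2 ± 1.28 to 17.7 ± 0.89 TPM (log2 -1.30, SE 0.12, limma adjusted p = 0.00266). hbegfa, which encodes an EGF receptor ligand, dropped from 41.6 ± 4.24 to 17.1 ± 0.94 TPM (log2 -1.23, SE 0.13, limma adjusted p = 0.0035). The maternal genome activators nanog (349 ± 9.90 TPM at 2 hpf) and sox19b (344 ± 14.6 TPM), the germ plasm organizer buc (627 ± 31.3 TPM) and znf281b (132 ± 6.35 TPM) had log2 differences of 0.00, -0.01, -0.04 and 0.05, and none passed the test. Of 16328 genes tested by limma, 0 rose and 2 fell at least 2-fold, against 625 genes at an unadjusted p under 0.05. Groups did not overlap for 13.8% of genes, where chance gives 10%. No member of any of the 24 lists was called over all genes, and adjusted over the list alone 6 of the 80 oxidative phosphorylation genes and 1 of the 37 RNA storage and decay genes fell. The lists with the lowest p by camera were ribosomal proteins (median log2 -0.15), oxidative phosphorylation (-0.13) and zona pellucida (-0.21), each with adjusted p = 0.618 with an estimated correlation. Without 2 hpf replicate 3 the call of hbegfa ended (adjusted p = 0.0527) and 1 gene fell, and without 2 hpf replicate 2, 1 gene rose.

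From 2 to 4 hpf, part of the axis, germ layer and epithelial regulators rose and part of the maternal oocyte transcripts fell. With an estimated correlation camera's adjusted p was 0.0474 for the dorsal organizer list and from 0.064 to 0.496 for the others. The largest rises were copies of dre-mir-430a-2, of the microRNA family that directs clearance of maternal mRNA, from 0.45 ± 0.78 to 2517 ± 301 TPM (log2 10.88), a value taken as uncertain because copies can share reads. Such values are of reads assigned to these copies in total RNA libraries, and the mature microRNA was not measured separately. With these copies left out, a choice made after seeing the data, the largest rises were inka1a (245 ± 45.2 TPM, log2 7.91), znf1004 (7.79), drll.3 (7.64) and asb11 (7.54). The largest falls were gbgt1l1 (from 31.6 ± 1.54 to 2.00 ± 0.38 TPM, log2 -3.45), trub2 (-3.18), the oogenesis-related gene org (-3.17), the ubiquitin-conjugating enzyme gene ube2t (-3.13) and lamtor3 (-3.10), which encodes a subunit of the lysosomal Ragulator complex. All of these passed limma's test with adjusted p of at most 1.63e-06.

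Among the early zygotic dorsoventral and mesendoderm regulators, 24 of 28 rose and 2 fell, with a median log2 change of 2.35. The yolk syncytial layer regulator mxtx2 reached 86.9 ± 15.5 TPM (log2 6.41) and the notochord factor noto 80.4 ± 41.4 TPM (6.17). Of the BMP and ventral factors, 12 of 16 rose and 2 fell (13 and 2 adjusted over the list alone), among them vox (5.90) and the ligand gene bmp2b (43.4 ± 3.47 TPM, 5.36). Of 13 dorsal organizer factors 9 rose and 0 fell, with her5 at 123 ± 7.21 TPM (6.71), gsc at 15.6 ± 4.74 TPM (3.41) and the BMP antagonist gene chrd at 10.8 ± 3.83 TPM (3.44). Of 15 enveloping layer and epithelial genes 9 rose and 2 fell, with the keratin gene krt18a.1 (6.84) and the epithelial transcription factor gene grhl3 (84.8 ± 11.4 TPM, 5.82). With an estimated correlation camera's adjusted p was 0.0474 for the dorsal organizer list, 0.064 for both the mesendoderm and the BMP lists and 0.117 for the enveloping layer list. The mesoderm gene tbxta rose only to 7.59 ± 4.54 TPM by 4 hpf (log2 2.58, limma adjusted p = 1.68e-05). Of the 11 pluripotency and genome activation factors 4 rose and 2 fell (adjusted p = 0.230 with an estimated correlation), against 7 and 0 after median-of-ratios scaling. The SoxB1 genes sox19a (112 ± 16.8 TPM, 6.70) and sox3 (5.59), klf17 (6.25) and nanog (532 ± 23.3 TPM, 0.61) rose. pou5f3 had a log2 change of 0.14 (limma adjusted p = 0.155). Of 238 numbered zinc finger genes, which can share reads, 114 rose and 36 fell (adjusted p = 0.117 with an estimated correlation), against 141 and 9 after median-of-ratios scaling. Of 17 p53 response genes 7 rose and 2 fell, including the cell cycle inhibitor gene cdkn1a (16.9 ± 1.33 TPM, 3.26) and gadd45aa (3.25), with adjusted p = 0.117 with an estimated correlation.

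The maternal groups moved the other way. Counts of list members have no fold minimum, and at that cut 8924 of all 16328 genes fell and 1803 rose. Lists with a like share of falls, such as the meiosis, cell cycle, heat shock and NuRD genes, therefore do not stand out from all genes. Of 27 oocyte-specific and maternal-effect genes 25 fell and 1 rose, led after org by the deadenylation adaptor gene btg4 (from 799 ± 54.0 to 99.2 ± 41.9 TPM, log2 -3.08) and zar1l (-3.05). Of 17 germ plasm genes 15 fell, including buc (from 627 ± 31.3 to 212 ± 68.4 TPM, -1.61) and the RNA-binding protein gene dazl (-1.61), and of 20 zona pellucida genes, which encode egg envelope proteins, 18 fell. Each of these 3 lists had adjusted p = 0.496 with an estimated correlation. After median-of-ratios scaling oocyte-specific genes had 17 falls and 2 rises, germ plasm genes 11 and 2, and zona pellucida genes 12 and 0. Of 80 nuclear-encoded oxidative phosphorylation genes 74 fell, with cox7a2a, a cytochrome c oxidase subunit gene, at -2.48 (adjusted p = 0.374 with an estimated correlation). Of 42 proteasome genes 34 fell (36 adjusted over the list alone, adjusted p = 0.496 with an estimated correlation), against 10 that fell and 8 that rose after median-of-ratios scaling. Of 10 meiosis genes 6 fell (7 adjusted over the list alone), and of 33 cell cycle genes 19 fell and 5 rose, such as ccnd1 (192 ± 56.3 TPM, 6.18), against 11 and 11 after median-of-ratios scaling. Of 20 heat shock genes 12 fell and 3 rose, such as hspb1 (4.91), of 8 interferon genes 4 fell and 1 rose, and of 4 stromal markers 2 fell. Of 8 follicle markers 1 rose and 2 fell, and of 5 blood markers 2 rose and 2 fell. Several directions turned with the scaling. For the 90 genes of the ribosomal protein list, of which 8 are S6 kinase genes, 2 rises and 27 falls (1 and 21 adjusted over the list alone) became 61 and 5 after median-of-ratios scaling. Without these kinase genes, a choice made after seeing the data, 2 and 21 became 60 and 2. For 37 RNA storage and decay genes 1 and 19 became 18 and 7. For 14 NuRD genes 0 and 8 became 8 and 4, and for 13 mitochondrially encoded genes 0 and 7 became 4 and 0. For the follicle markers 1 and 2 became 2 and 1. The medians of cell cycle genes, heat shock genes and blood markers turned to 0.00, 0.05 and 0.23. znf281b stayed at 127 ± 12.8 TPM (log2 -0.05, limma adjusted p = 0.708), a change that turned to 0.51 after that scaling, and znf281a rose to 11.5 ± 0.43 TPM (0.50).

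In all, 1153 genes rose and 2859 fell at least 2-fold (28.7% rises) from 2 to 4 hpf by limma. The median change of all genes was -0.43 on the log2 scale, and after median-of-ratios scaling, which moved it to 0.03, 1430 rose and 983 fell (59.3% rises). The 1803 genes called as risen by limma with no fold minimum held 15.6 ± 0.11% of TPM at 2 hpf and 32.2 ± 3.20% at 4 hpf. By arithmetic this equals a drop of 0.32 on the log2 scale in the summed share of the other genes. Shares sum to a constant and these genes were picked for their rise, so this does not tell which side changed. Groups did not overlap for 71.0% of genes (10% by chance).

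**Figure D1:**
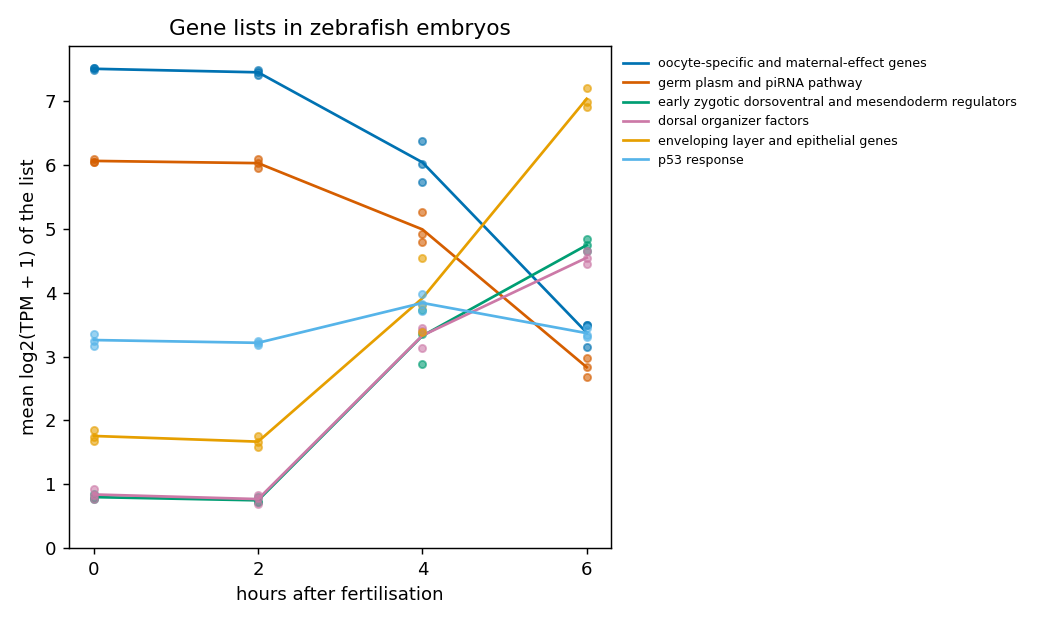
Mean log2(TPM + 1) over the members of 6 gene lists (vertical axis) at 0, 2, 4 and 6 hours after fertilisation (horizontal axis), with points for the 3 libraries per time and lines for their means. The oocyte-specific list lay between 7.41 and 7.52 at 0 and 2 hpf and between 3.15 and 3.49 at 6 hpf, the enveloping layer list rose from 1.58 to 1.76 at 2 hpf to 6.91 to 7.20 at 6 hpf, and these 2 kept their direction after median-of-ratios scaling, while the p53 response median from 4 to 6 hpf turned from -0.44 to 0.25.

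From 4 to 6 hpf, as gastrulation begins, part of the epithelial and mesodermal transcripts rose further and part of the maternal transcripts dropped. Their lists had camera adjusted p from 0.438 to 0.480 with an estimated correlation. The largest rises were the keratin genes cyt1 (254 ± 15.1 TPM at 6 hpf, log2 6.87) and krt17 (6.34), the cathepsin gene ctsll (481 ± 94.2 TPM, 6.60), the ventral homeobox gene eve1 (6.42) and mespab (6.38). Reads assigned to dre-mir-430a-2 fell from 2517 ± 301 to 15.3 ± 3.17 TPM (log2 -7.28, uncertain as above), while the mature microRNA was not measured separately. Falls next in size were those of a histone H2A gene, h2af1al (-5.00), the lipase gene lipg (-4.70), the claudin gene cldnd (-4.61), buc (from 212 ± 68.4 to 8.66 ± 2.13 TPM, -4.44) and the piRNA pathway gene tdrd1 (-4.09). All had a limma adjusted p of at most 1.37e-08.

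Of 15 enveloping layer genes 11 rose and 3 fell, with a median log2 change of 4.11 (adjusted p = 0.438 with an estimated correlation). Of 28 mesendoderm regulators 19 rose and 4 fell (adjusted p = 0.480 with an estimated correlation): tbxta rose to 259 ± 15.4 TPM (5.08), the posterior homeobox gene cdx4 to 73.4 ± 8.67 TPM (5.85) and the endoderm factor sox32 to 78.4 ± 0.68 TPM (4.65). Of 16 BMP and ventral factors 11 rose, with bmp4 at 3.29, and of 13 dorsal organizer factors 11 rose, with chrd at 57.9 ± 8.44 TPM (2.36) and gsc at 36.9 ± 5.54 TPM (1.22), and 2 fell, with her5 at -4.03 (adjusted p = 0.412 for both lists with an estimated correlation). Of the 11 pluripotency factors 5 rose and 2 fell: sox2 (45.0 ± 5.04 TPM, 5.44) and pou5f3 (from 306 ± 22.4 to 619 ± 33.9 TPM, 1.02) rose, while nanog (from 532 ± 23.3 to 61.4 ± 13.6 TPM, -3.12) and sox19b (-3.12) fell. Ribosomal protein genes rose in 80 of 90 cases and fell in 9, with rps26l at 1.93 (adjusted p = 0.412 with an estimated correlation). The list was taken by symbol and held 8 S6 kinase genes, which all fell, such as rps6ka1 (-2.77). Without them, a choice made after seeing the data, 80 of 82 rose and 1 fell. In the oocyte and knockdown tests the list also held 8 S6 kinase genes. Of these 1 fell from stage III to IV, 2 fell from I to IV and 1 rose in the knockdown. Of 42 proteasome genes 23 rose and 9 fell (psmb6 at 2.22), and of 80 oxidative phosphorylation genes 37 rose and 27 fell (ndufs6, of respiratory complex I, at 2.57), with adjusted p of 0.480 and 0.555 with an estimated correlation. After median-of-ratios scaling these were 34 and 1 for proteasome genes and 56 and 10 for oxidative phosphorylation genes. Of 14 NuRD genes 8 rose and 4 fell (adjusted p = 0.508 with an estimated correlation), and of 238 numbered zinc finger genes 113 rose and 44 fell (109 and 44 adjusted over the list alone, adjusted p = 0.480 with an estimated correlation), against 173 and 26 after that scaling.

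Of 27 oocyte-specific genes 26 fell and 1 rose, with a median of -3.06. All 17 germ plasm genes fell, and 19 of 20 zona pellucida genes, such as zp3c (-3.08). After median-of-ratios scaling oocyte-specific genes had 24 falls and 2 rises, germ plasm genes 14 and 2, and zona pellucida genes 11 and 1. Each of these 3 lists had adjusted p = 0.480 with an estimated correlation. The oocyte growth factor gene gdf9 fell to 1.65 ± 0.16 TPM (-2.67). With no fold minimum, as for list members, 9119 of all 16328 genes fell and 3717 rose. Falls outnumbered rises among RNA storage and decay genes (25 and 9 of 37, 25 and 10 adjusted over the list alone), cell cycle genes (18 and 9 of 33, with ccna1 at -3.71 and wee2 at -3.41), p53 response genes (9 and 2 of 17, with sesn1 at -2.17), heat shock genes (10 and 7 of 20, with hspa5 at -2.66), interferon genes (5 and 1 of 8) and meiosis genes (6 and 2 of 10). These directions turned after median-of-ratios scaling for cell cycle genes (16 rises and 11 falls), p53 response genes (8 and 7) and heat shock genes (9 and 7), and the RNA storage and decay median went from -0.73 to 0.02. The 13 mitochondrially encoded genes had 0 calls by limma, where 13052 of all genes had an unadjusted p under 0.05, and 13 rises after that scaling. Follicle markers (3 rises and 4 falls of 8), stromal markers (2 falls of 4) and blood markers (1 rise and 1 fall of 5) had few calls. After that scaling follicle markers had 4 rises and 3 falls and blood markers 3 and 0. znf281a rose to 29.3 ± 6.83 TPM (1.25), and znf281b was at 96.6 ± 16.7 TPM (-0.40, limma adjusted p = 0.00728), a fall that became a rise of 0.36 after median-of-ratios scaling.

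Between 4 and 6 hpf 2185 genes rose and 5581 fell at least 2-fold (28.1% rises), with a median change of -0.56, and 3961 rose and 3362 fell (54.1% rises) after median-of-ratios scaling, which moved the median to -0.03. The 3717 genes called as risen with no fold minimum and without that scaling went from 21.8 ± 1.81% to 42.8 ± 0.51% of TPM. By arithmetic the summed share of the others dropped by 0.45 on the log2 scale, which again does not tell which side changed. Groups did not overlap for 78.0% of genes (10% by chance).

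Over the whole interval from 0 to 6 hpf most members of the maternal lists fell and most of the early zygotic and epithelial lists rose. No such list passed camera with an estimated correlation (adjusted p from 0.0827 to 0.477). Among the largest changes were rises of the apolipoprotein gene apoeb (from 1.80 ± 0.59 to 2348 ± 119 TPM, log2 9.73) and krt18a.1 (9.70), and falls of the claudin genes cldng (from 1846 ± 102 to 8.84 ± 0.78 TPM, -7.55) and cldnd (-7.10) and of btg4 (-7.48). All 13 dorsal organizer factors, 26 of 28 mesendoderm regulators, 15 of 16 BMP factors and 13 of 15 enveloping layer genes rose, and 26 of 27 oocyte-specific, all 17 germ plasm and all 20 zona pellucida genes fell. Adjusted p with an estimated correlation was from 0.0827 to 0.147 for the first 4 lists and from 0.435 to 0.477 for the other 3. After median-of-ratios scaling oocyte-specific genes had 25 falls and 2 rises, germ plasm genes 14 and 3, and zona pellucida genes 16 and 2. Of the 90 genes of the ribosomal protein list 75 rose and 12 fell (adjusted p = 0.260 with an estimated correlation). The falls included all 8 S6 kinase genes, and without these 75 of 82 rose and 4 fell. Of 80 oxidative phosphorylation genes 4 rose and 68 fell (4 and 69 adjusted over the list alone), a direction that turned to 33 rises and 26 falls after median-of-ratios scaling. The proteasome genes (7 rises and 25 falls of 42, 6 and 25 adjusted over the list alone) turned to 31 and 4 under that scaling. By limma 2644 genes rose and 8447 fell at least 2-fold (23.8% rises), with a median of -1.06, and 4696 rose and 4287 fell (52.3% rises) after that scaling, with a median of -0.06. With no fold minimum and without that scaling 3578 of 16328 genes rose and 10978 fell. These 3578 genes went from 23.2 ± 1.34% to 57.7 ± 0.57% of TPM. By arithmetic the summed share of the others dropped by 0.86 on the log2 scale, which does not tell which side changed. Groups did not overlap for 89.4% of genes (10% by chance).

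From oocyte stage I to stage II, 13 of the 25 genes that rose were mitochondrially encoded, a list with camera adjusted p = 0.470 with an estimated correlation. All 13 mitochondrially encoded genes rose, with a median log2 change of 2.89. mt-atp6, an ATP synthase subunit gene, went from 210 ± 61.6 to 2371 ± 388 TPM (log2 3.51, limma adjusted p = 0.0111), and mt-nd1, of respiratory complex I, from 65.5 ± 20.6 to 648 ± 42.9 TPM (3.32). A copy of MFAP4, of a microfibril-associated protein family whose copies can share reads, rose to 102 ± 23.6 TPM (5.23), and the disulfide isomerase gene pdia2 to 20.0 ± 7.42 TPM (3.57). nxph1 (-2.08), the homeobox gene dlx6a (-1.97) and the polyamine-acetylating enzyme gene sat1a.2 (from 345 ± 4.19 to 119 ± 2.09 TPM, -1.53) fell. Members of the other lists had 0 calls by limma over all 16067 genes, where 1833 genes had an unadjusted p under 0.05, and adjusted over the list alone 1 pluripotency and 1 cell cycle gene fell and 1 p53 response and 1 heat shock gene rose. The mitochondrial list had adjusted p = 0.470 with an estimated correlation. At least 2-fold, 25 genes rose and 3 fell (89.3% rises). After median-of-ratios scaling 2 rose and 1 fell (66.7% rises, with the median of all genes moving from 0.13 to 0.00), and 0 mitochondrial genes passed although their median stayed at 2.73. Every call named here depended on single libraries. Without stage II replicate 1 or stage II replicate 2 limma called 0 genes at least 2-fold, with adjusted p of the named genes from 0.0634 to 0.374. Without stage I replicate 1 it called 49 rises and 10 falls, and without stage I replicate 2, 15 rises. With no filter on low values it called 0.

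From stage II to stage III, part of the genes typical of somatic cells around the oocyte rose. Their lists had adjusted p from 0.151 to 0.527 with an estimated correlation. A copy of MFAP4 went from 102 ± 23.6 to 5995 ± 1958 TPM (log2 5.84, limma adjusted p = 0.00188), and cmah, a sialic acid hydroxylase gene, from 4.13 ± 1.51 to 100 ± 23.1 TPM (4.31). Of 24 ovarian follicle markers 11 rose (15 adjusted over the list alone), with a median of 1.80 and adjusted p = 0.151 with an estimated correlation. The steroidogenic regulator nr5a1a rose to 28.9 ± 14.5 TPM (4.51), the aromatase gene cyp19a1a from 4.10 ± 0.82 to 105 ± 31.2 TPM (4.35), foxl2b to 31.9 ± 3.61 TPM (3.40) and the inhibin gene inha to 17.3 ± 7.5 TPM (3.37). Of 16 stromal and vascular wall markers 5 rose (10 adjusted over the list alone, adjusted p = 0.432 with an estimated correlation), with the smooth muscle genes acta2 (44.2 ± 0.77 TPM, 3.72) and tagln (3.21). Of 19 blood, endothelial and immune markers 3 rose (5 rose and 1 fell adjusted over the list alone, adjusted p = 0.527 with an estimated correlation), with a copy of the globin gene hbba1 at 24.4 ± 6.95 TPM (3.32). Of 13 mitochondrially encoded genes 8 rose (13 adjusted over the list alone), with mt-co1 at 6838 ± 382 TPM (1.91) and adjusted p = 0.432 with an estimated correlation. The bloodthirsty-family gene btr02 (-3.43), nagpa (-2.89) and the transcription factor gene sall4 (from 10.4 ± 0.93 to 1.84 ± 0.28 TPM) fell. With no fold minimum, as for list members, 322 genes rose and 85 fell. By limma 319 genes rose and 66 fell at least 2-fold of 16067 tested, with a median of -0.16, and 375 rose and 39 fell after median-of-ratios scaling, with a median of 0.04. The counts were 17 and 0 without stage II replicate 1 and 41 and 1 without stage II replicate 2. They were 7 and 1 without stage III replicate 1 and 94 and 22 without stage III replicate 2. In these fits nr5a1a, cmah and the MFAP4 copy passed each time. The calls of cyp19a1a, hbba1, mt-co1, btr02, nagpa and sall4 ended without any 1 of the 4 libraries (limma adjusted p from 0.0625 to 0.279). Those of inha, acta2 and tagln ended without stage II replicate 1 or stage III replicate 1 (at least 0.0559), and that of foxl2b without stage III replicate 1 (0.07).

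From stage III to stage IV, part of the follicle, blood and ribosomal protein genes rose, and part of the egg envelope, germ plasm and cell cycle genes fell. These lists had adjusted p from 0.533 to 0.550 with an estimated correlation. The antimicrobial peptide gene leap2, listed at 0 in both stage III libraries, reached 186 ± 44.6 TPM, the bicarbonate transporter gene slc4a4a rose to 211 ± 59.4 TPM (log2 6.47) and the angiotensin-converting enzyme gene ace to 70.7 ± 17.2 TPM (5.81). Of 24 follicle markers 15 rose and 2 fell (16 and 2 adjusted over the list alone). The luteinizing hormone receptor gene lhcgr rose to 37.0 ± 7.62 TPM (4.83), the gonadal growth factor gene igf3 to 82.1 ± 14.1 TPM (3.83) and the progesterone receptor gene pgr to 63.2 ± 9.28 TPM (3.59), while cyp19a1a fell from 105 ± 31.2 to 5.04 ± 5.61 TPM (-4.51, limma adjusted p = 0.0026). Of 19 blood markers 12 rose (15 adjusted over the list alone), with the antigen-presentation gene cd74a at 86.7 ± 19.7 TPM (2.39) and both copies of hbba1 at 3.01. Of 16 stromal markers 0 were called by limma over all genes or adjusted over the list alone (median 0.62, adjusted p = 0.550 with an estimated correlation), where 6463 of all genes had an unadjusted p under 0.05, and 4 rose after median-of-ratios scaling. Of 90 ribosomal protein genes 49 rose and 2 fell (71 and 3 adjusted over the list alone), such as rps28 (from 786 ± 11.5 to 2485 ± 567 TPM, 1.64) and rpl5a (1.33), and of 88 oxidative phosphorylation genes 27 rose and 0 fell, such as cox7a1 (2.90).

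Of 20 zona pellucida genes 14 fell (15 adjusted over the list alone), with zp2.2 at -2.39 and zp2.5 from 3488 ± 191 to 876 ± 663 TPM (-2.23). Of 27 oocyte-specific genes 9 fell and 1 rose (9 and 3 adjusted over the list alone), with the zinc finger gene cth1 (from 407 ± 22.6 to 51.8 ± 8.34 TPM, -2.96), gdf9 (-2.44) and the maternal-effect gene zar1 (from 631 ± 95.6 to 145 ± 39.5 TPM, -2.14). Of 17 germ plasm genes 8 fell (10 adjusted over the list alone), with dnd1 at -2.47, tdrd1 at -1.81 and the helicase gene ddx4 at -1.18, while buc (1438 ± 246 TPM, 0.09) and dazl (137 ± 3.01 TPM, -0.02) did not pass. Of 34 cell cycle genes 12 fell (13 fell and 1 rose adjusted over the list alone), such as ccna2 (-2.54), the kinase gene wee1 (-2.19) and ccnb1 (from 1363 ± 41.2 to 366 ± 83.9 TPM, -1.91). nanog (-2.13) and sox19b (-1.80) fell, as did the lipid-metabolism regulator hnf4b (-4.29), another MFAP4 copy (-4.58) and 10 of 22 heat shock genes with 1 rise, such as pdia4 (-2.32). Adjusted p with an estimated correlation was 0.533 for the follicle, blood, zona pellucida, germ plasm, cell cycle, heat shock and oxidative phosphorylation lists, 0.550 for ribosomal proteins and 0.609 for oocyte-specific genes.

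With no fold minimum, as for list members, 2298 of all 16067 genes rose and 2140 fell from stage III to IV. Counts at least 2-fold between stages III and IV were 1572 rises and 1486 falls (51.4% rises, limma), and 2034 and 1177 (63.3% rises) after median-of-ratios scaling, which moved the median from -0.05 to 0.10. Falls numbered 917 without stage III replicate 1, counts were 941 and 802 without stage III replicate 2 and 588 and 877 without stage IV replicate 1, and rises numbered 879 without stage IV replicate 2. The call of zp2.2 ended without stage III replicate 1, stage III replicate 2 or stage IV replicate 1 (limma adjusted p from 0.0617 to 0.129), and that of zp2.5 without stage III replicate 1 (0.0571) or 2 (0.0694). That of 1 hbba1 copy ended without stage III replicate 2 (0.102) or stage IV replicate 2 (0.0588), and that of cox7a1 with a pseudocount of 0.1 TPM (0.135).

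**Figure D2:**
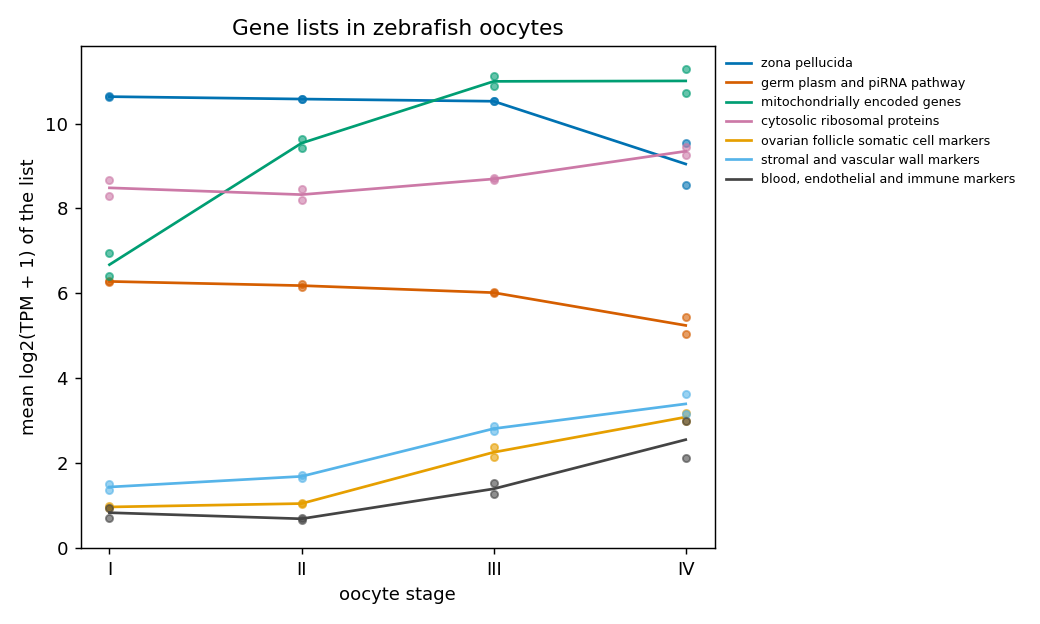
Mean log2(TPM + 1) over the members of 7 gene lists (vertical axis) in oocyte stages I to IV (horizontal axis), with points for the 2 libraries per stage and lines for their means. The mitochondrially encoded list lay between 6.41 and 6.94 in stage I and between 10.7 and 11.3 in stage IV, the follicle marker list between 0.96 and 0.99 and between 2.99 and 3.19, and the zona pellucida list between 10.6 and 10.7 and between 8.56 and 9.54, and the medians of these 3 lists from stage I to IV kept their direction after median-of-ratios scaling.

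Across the whole of growth, from stage I to stage IV, the largest rises were a copy of MFAP4 (from 1.86 ± 1.22 to 12576 ± 5555 TPM, log2 12.10), the selenium carrier gene selenop (1241 ± 259 TPM, 8.24) and the connexin gene cx34.5 (448 ± 1.70 TPM, 7.56), and the largest falls hnf4b (-4.53), the stearoyl-CoA desaturase gene scd (-3.95) and cth1 (-3.92). All 13 mitochondrially encoded genes rose (median 4.36), with mt-cyb going from 204 ± 34.3 to 6213 ± 1262 TPM (4.92). Rises were called for 18 of 24 follicle markers (18 and 1 fall adjusted over the list alone), such as igf3 (6.30) and inha (172 ± 0.42 TPM, 6.26), 13 of 16 stromal markers, such as acta2 (5.86), and 14 of 19 blood markers (15 and 1 fall adjusted over the list alone), such as hbaa1 (223 ± 251 TPM, 5.32). Rises also held for 70 of 90 ribosomal protein genes with 3 falls (74 and 3 adjusted over the list alone) and 59 of 88 oxidative phosphorylation genes with 1 fall (64 and 2 adjusted over the list alone). Of 37 RNA storage and decay genes 19 fell and 3 rose (22 and 3 adjusted over the list alone), the rises led by the poly(A)-binding protein gene pabpc1b (174 ± 104 TPM, 6.14). Of 17 germ plasm genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), and of 20 zona pellucida genes 15 fell. zar1 fell from 1545 ± 287 to 145 ± 39.5 TPM (-3.42), and znf281b from 19.4 ± 1.43 to 6.72 ± 0.52 TPM (-1.40, limma adjusted p = 0.00256). These lists each had adjusted p = 0.404 with an estimated correlation. Summed over their members, follicle markers went from 123 TPM in stage I through 134 and 358 to 823 TPM in stage IV, and blood markers from 36.5 through 25.5 and 111 to 835 TPM, where the 2 stage IV libraries held 411 and 1259 TPM. Stromal markers summed to 2487, 1701, 2440 and 3187 TPM, with 1606 and 3367 TPM in the 2 stage I libraries. In stage III most of this sum came from the gene thy1. The stromal list also summed to 1329 TPM in 0 hpf embryos, so these sums do not compare the shares of cell types.

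Of 5 vitellogenin genes, which encode yolk precursors made in the liver, 1 rose, vtg1, at 59.2 ± 66.9 TPM in stage IV (3.25), a call that ended without stage I replicate 1 (limma adjusted p = 0.0845) or stage IV replicate 2 (0.0866). With no fold minimum, as for list members, 3680 of all 16067 genes rose and 3603 fell from stage I to IV. At least 2-fold, 2667 genes rose and 2651 fell (50.2% rises, limma) with a median of -0.07, and 3390 and 1992 (63.0% rises) after median-of-ratios scaling, with a median of 0.13. Rises numbered 1644 without stage IV replicate 1. Genes that rose from 0 to 6 hpf in embryos had a median log2 change of 0.75 from stage I to IV (597 rose and 210 fell of 1325 tested, limma), and 0.26 without stage IV replicate 1 and 0.48 without stage IV replicate 2. Genes that fell in embryos had a median of -0.24 (1103 rose and 2213 fell of 8167), and -0.08 without stage I replicate 1 and -0.39 without stage I replicate 2. Adjusted p with an estimated correlation was 0.114 and 0.247.

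In the knockdown the targeted gene was lower in every library. znf281b was at 149, 147 and 171 TPM in the 3 libraries labelled znf281b KD and at 219, 269 and 267 TPM in the 3 labelled pCas13d alone, so the knockdown mean of 156 ± 13.6 TPM was 61.9% of the control mean of 252 ± 27.9 TPM. The log2 change was -0.69 (SE 0.11, limma adjusted p = 0.00991), and the two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 can give. Without znf281b KD replicate 2 the change was -0.65 and the call ended (limma adjusted p = 0.0549). Its paralogue znf281a was at 6.73 ± 0.58 TPM against 12.2 ± 4.84 TPM (-0.71, limma adjusted p = 0.111, exact permutation p = 0.1). In the other tables, with no test across tables, znf281b lay between 78.8 and 138 TPM in embryos and between 6.36 and 21.6 TPM in oocytes.

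**Figure D3:**
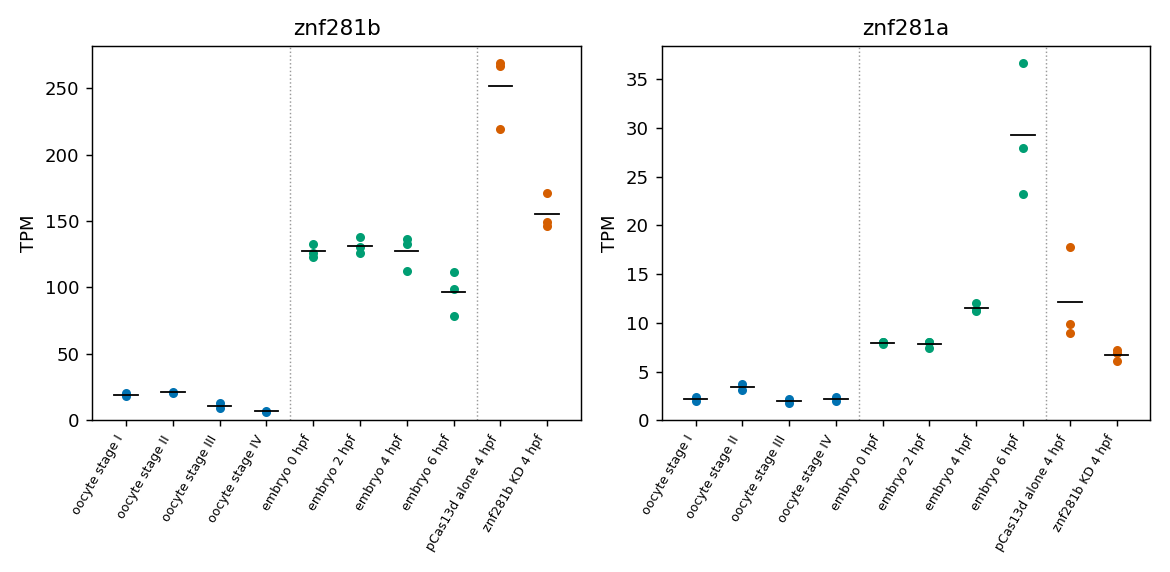
TPM (vertical axes, from 0) of znf281b and znf281a in all 26 libraries by group (horizontal axis), with points for libraries, short lines for group means and dotted lines parting the 3 tables, which were normalised separately. In the knockdown table znf281b was at 147 to 171 TPM in the knockdown libraries and at 219 to 269 TPM in the control libraries.

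Part of the axis, germ layer and epithelial genes tested were lower in knockdown than in control embryos, and part of the p53 response and germ plasm genes were higher. These lists had adjusted p from 0.354 to 0.444 with an estimated correlation. The largest falls were apela, the ligand of the apelin receptor that guides mesendoderm cells (from 59.1 ± 10.6 to 2.75 ± 1.19 TPM, log2 -4.05, SE 0.26, limma adjusted p = 0.000508), the chemokine receptor gene cxcr4a (from 124 ± 25.7 to 7.35 ± 2.88 TPM, -3.93), foxd5 (-3.69), the keratin gene krt92 (-3.10) and the prolyl isomerase gene fkbp7 (-2.82). The largest rises were the Hes-family gene her12 (from 6.18 ± 2.62 to 42.4 ± 3.79 TPM, 2.67), the oxidative stress regulator gene nfe2l2b (2.36), the autophagy kinase gene ulk2 (2.05), rgs20 (2.05) and the haem oxygenase gene hmox1a (1.96).

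Of 25 mesendoderm regulators 8 fell and 2 rose (10 and 3 adjusted over the list alone), with gsc going from 28.8 ± 8.15 to 9.34 ± 0.91 TPM (-1.49) and tbxta from 19.0 ± 8.53 to 7.49 ± 1.31 TPM (-1.16, limma adjusted p = 0.043). Of 11 dorsal organizer factors 5 fell and 0 rose (8 and 0 adjusted over the list alone), with foxd3 (-1.92), zic2b (from 302 ± 95.8 to 89.0 ± 14.1 TPM, -1.72) and chrd (-1.48). Of 13 BMP and ventral factors 6 fell and 2 rose (8 and 2 adjusted over the list alone), with tfap2a (from 59.1 ± 14.5 to 19.7 ± 1.27 TPM, -1.51). Of 11 enveloping layer genes 3 fell (6 adjusted over the list alone). Of 10 pluripotency factors 3 fell (5 fell and 1 rose adjusted over the list alone), namely sox3 (from 149 ± 4.87 to 54.7 ± 6.88 TPM, -1.43), sox19a (-1.14) and pou5f3 (-0.44), while nanog (-0.17, limma adjusted p = 0.108) and sox19b (0.80, 0.0628) did not pass. Of 90 ribosomal protein genes 18 fell and 2 rose (37 and 4 adjusted over the list alone), with rplp2 at -1.51, and of 231 numbered zinc finger genes 41 fell and 3 rose (49 and 8 adjusted over the list alone), with znf1060 at -1.97. cxcr4b (-1.19), 1 of 3 blood markers tested, fell, and so did ccnd1 (from 369 ± 157 to 52.3 ± 10.9 TPM, -2.74).

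Of 16 p53 response genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.08. The stress-response gene sesn1 went from 93.6 ± 9.23 to 362 ± 32.8 TPM (1.94, SE 0.10, limma adjusted p = 0.000316), the pro-apoptotic gene bbc3 from 42.2 ± 7.23 to 138 ± 17.1 TPM (1.69), gadd45aa to 118 ± 6.56 TPM (1.56), tp53inp1 to 233 ± 19.1 TPM (1.45) and cdkn1a from 116 ± 6.21 to 282 ± 42.3 TPM (1.26). Of 17 germ plasm genes 5 rose (7 adjusted over the list alone), with tdrd6 at 1.73, and of 27 oocyte-specific genes 3 rose (8 rose and 1 fell adjusted over the list alone), with lsm14b at 1.24 and buc from 144 ± 56.3 to 396 ± 7.02 TPM (1.55). Of 7 interferon genes 3 rose and 1 fell (6 and 1 adjusted over the list alone), with ifit8 at 1.76. Of 32 cell cycle genes 3 rose and 2 fell (11 and 4 adjusted over the list alone), and of 37 RNA storage and decay genes 7 rose and 1 fell (9 and 4 adjusted over the list alone). After median-of-ratios scaling rises and falls were 1 and 2 for cell cycle genes and 5 and 3 for RNA storage and decay genes. Of 79 oxidative phosphorylation genes 3 rose and 1 fell (2 and 1 adjusted over the list alone), of 42 proteasome genes 1 rose (0 adjusted over the list alone), and of 14 NuRD genes 2 rose. After that scaling rises and falls were 2 and 3 for oxidative phosphorylation genes and 0 and 1 for proteasome genes. Of 17 heat shock genes 1 rose and 1 fell (4 and 2 adjusted over the list alone), of 20 zona pellucida genes 1 rose, and of 6 follicle markers 2 rose and 1 fell. The 13 mitochondrially encoded genes, 9 meiosis genes and 4 stromal markers had 0 calls by limma, where 4145 of all genes had an unadjusted p under 0.05, and no vitellogenin gene passed the filter (0 tested). Adjusted p with an estimated correlation was 0.354 for the pluripotency, BMP, dorsal organizer, enveloping layer, ribosomal protein, zinc finger, p53 and interferon lists, 0.444 for the mesendoderm and germ plasm lists, and 0.633 for the oocyte-specific list.

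By limma 952 genes were higher and 459 lower in the knockdown at an adjusted p under 0.05 (341 and 273 at least 2-fold, 55.5% higher), of 15068 tested. The groups did not overlap for 35.0% of genes (10% by chance). After median-of-ratios scaling, which moved the median change from 0.09 to 0.00, 724 were higher and 594 lower (244 and 323 at least 2-fold, 43.0% higher). Higher and lower genes numbered 295 and 232 without pCas13d replicate 1, and 1692 were higher without pCas13d replicate 2. They numbered 184 and 194 without KD replicate 1, 146 and 161 without KD replicate 2, and 320 and 218 without KD replicate 3. With no filter on low values they were 305 and 226. The calls of pou5f3, chrd and krt92 ended without any 1 of the KD libraries (limma adjusted p from 0.0555 to 0.129), and that of tbxta without any 1 of these or pCas13d replicate 1 (0.0916 to 0.133). That of buc ended without KD replicate 1 (0.054) or 2 (0.0572), while sox19b passed without pCas13d replicate 2 (0.0271) or 3 (0.0139). With no filter on low values the calls of pou5f3 (0.106), chrd (0.0551), krt92 (0.0836), buc (0.0565) and tbxta (0.104) ended, and with quantile normalization that of pou5f3 (0.0822).

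Part of the genes that rise in normal embryos between 2 and 4 hpf were lower in the knockdown, and part of those that fall were higher. The 2 sets had adjusted p = 0.167 and 0.243 with an estimated correlation. Of 890 such rising genes tested, 300 were lower and 31 higher in the knockdown, with a median of -0.69 against 0.11 for the other genes. Of 2766 falling genes, 325 were higher and 7 lower, with a median of 0.32. Of 1462 genes that rose from 4 to 6 hpf, 191 were lower and 25 higher (median -0.32), and of 5479 that fell, 616 were higher and 73 lower (median 0.25). Camera's adjusted p was 1.35e-53, 6.12e-12, 3.85e-28 and 3.11e-14 with the preset correlation, and adjusted p = 0.167, 0.243, 0.194 and 0.243 with an estimated correlation. Of 445 genes lower in the knockdown and tested in both tables, 67.4% had risen from 2 to 4 hpf, against 6.17% of all 14428 genes (Fisher's exact test, two-sided p = 2.84e-269, across genes, which are not independent). Without pCas13d replicate 3 the medians for genes that rose and fell from 2 to 4 hpf were -0.50 and 0.20, and for those that rose and fell from 4 to 6 hpf -0.17 and 0.16.

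**Figure D4:**
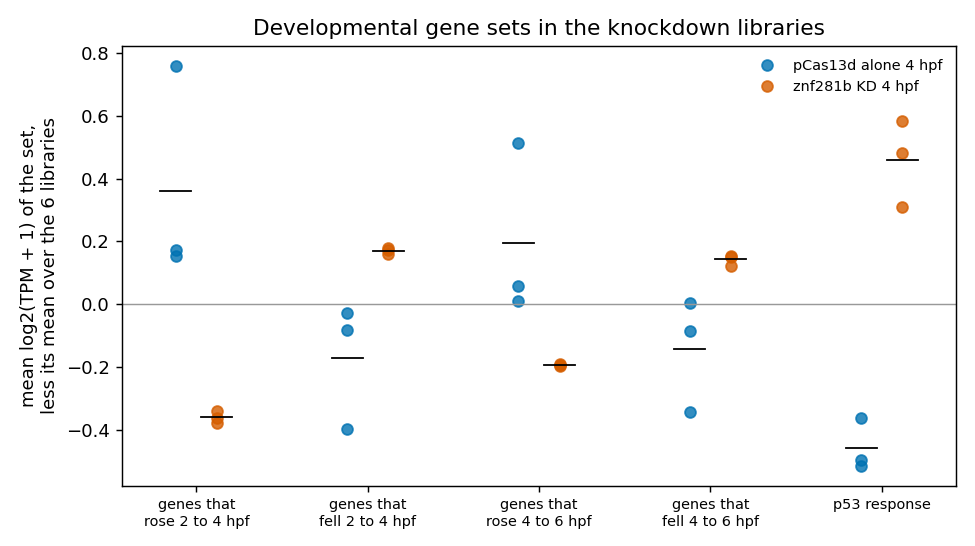
Mean log2(TPM + 1) of 4 sets of genes defined by their change between embryo stages, and of the p53 response list, less the mean over the 6 libraries (vertical axis), with points for libraries and short lines for means of the 3 control and 3 knockdown libraries. For genes that rose from 2 to 4 hpf the knockdown libraries lay between -0.38 and -0.34, and the controls at 0.17, 0.15 and 0.76.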

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

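The alternatives were planned before the data were examined, except where stated, and the cause of a change was not tested unless named. Where 1 of 2 oocyte libraries was left out, the lone library is assumed to vary like the other stages. Of 998 values of named genes with 1 library left out, 893 kept their direction and side of the threshold, 103 lost the call, 2 gained it and 0 turned. Of 1030 list medians 969 kept both. With median-of-ratios scaling 184 of 193 genes and 190 of 205 lists kept both, with a pseudocount of 0.1 TPM 192 of 193 and 201 of 205. Depth is unknown, so its limit on low genes cannot be given.

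Counts left out 1 library at a time ranged as follows. From 0 to 2 hpf rises were 0 to 1 and falls 1 to 3. For stages I to II rises were 0 to 49 and falls 0 to 10, for II to III 7 to 94 and 0 to 22, for III to IV 588 to 1123 and 802 to 1293, and for I to IV 1644 to 2921 and 2035 to 3186. In the knockdown 146 to 1692 genes were higher and 161 to 623 lower.

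With median-of-ratios scaling 983 genes fell from 2 to 4 hpf, 3961 rose and 3362 fell from 4 to 6 hpf, 4696 and 4287 from 0 to 6 hpf, 2 and 1 from stage I to II, and 39 fell from II to III. With quantile normalization 1213 fell from 2 to 4 hpf and 5145 from 0 to 6 hpf. With a pseudocount of 0.1 TPM 1 gene rose from 0 to 2 hpf and 5 fell from stage I to II. With no filter on low values limma called 0 rises and 0 falls from stage I to II (1833 genes had an unadjusted p under 0.05 with the filter), 101 and 19 from II to III, and 305 higher and 226 lower in the knockdown, where more genes are tested. Without the mitochondrially encoded genes whose symbol starts with mt-, 4 rose and 1 fell from stage I to II, and the calls of nxph1 (adjusted p = 0.0855) and dlx6a (0.0798) ended. With only the 2 groups compared 516 rose and 219 fell from II to III. With a stricter filter of 5 TPM, which tests fewer genes, 854 rose from III to IV and 1467 from I to IV.

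Other calls of named genes changed as follows. With no filter those of cyp19a1a (0.0737), 1 hbba1 copy (0.0813), btr02 (0.124) and sall4 (0.057) from II to III, zp2.2 from III to IV (0.0591) and vtg1 from I to IV (0.0546) ended. That of btr02 ended also with median-of-ratios scaling (0.0564) and quantile normalization (0.108), and that of zp2.2 with only the 2 groups compared (0.0626). pou5f3 passed from 2 to 4 hpf with median-of-ratios scaling (0.71) and quantile normalization (0.26). From I to II, pdia2, nxph1 and dlx6a did not pass with either scaling (adjusted p from 0.0533 to 0.0995), nor nxph1 (0.0958) and dlx6a (0.114) with only the 2 groups compared.

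With the preset correlation 8 lists passed camera from 0 to 2 hpf. From 2 to 4, 4 to 6 and 0 to 6 hpf 12 passed each time. In oocytes 5, 9, 10 and 14 passed from stage I to II, II to III, III to IV and I to IV. In the knockdown 12 passed. Camera with an estimated correlation left 1 list from 2 to 4 hpf and 0 in every other comparison. In the knockdown the genes that rose and fell from 2 to 4 hpf (medians -0.69 and 0.32) and from 4 to 6 hpf (-0.32 and 0.25) then had adjusted p of 0.167, 0.243, 0.194 and 0.243. The genes that rose and fell from 0 to 6 hpf (0.75 and -0.24 in oocytes) had 0.114 and 0.247.

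Among genes and lists past the threshold of limma or of camera's preset test with or without the alternative, directions turned as follows. With median-of-ratios scaling znf281b went to 0.51 from 2 to 4 hpf and 0.36 from 4 to 6 hpf, ribosomal proteins to 0.46 from 2 to 4 hpf, oxidative phosphorylation to 0.18, mitochondrially encoded genes to 1.27 and proteasome to 0.97 from 0 to 6 hpf, and cell cycle to -0.13 from stage I to II. With quantile normalization znf281b went to 0.29 and ribosomal proteins to 0.14 from 2 to 4 hpf, proteasome to 0.51 from 0 to 6 hpf, and mitochondrially encoded genes to 0.029 in the knockdown. With no filter blood markers went to 0.0093 from 2 to 4 hpf and follicle markers to 0.019 from 4 to 6 hpf. With only the 2 groups compared pluripotency factors went to 0.084 from 0 to 2 hpf. With the stricter filter numbered zinc finger genes went to -0.11, -1.01 and -0.70 from II to III, III to IV and I to IV. Leaving out 1 library turned NuRD genes (-0.0015 without 0 hpf replicate 2, range to 0.11) and mitochondrially encoded genes (-0.073 without 0 hpf replicate 3, range to 0.21) from 0 to 2 hpf. From stage I to II it turned pluripotency factors (range -0.46 to 0.21, above 0 without stage I replicate 1 or, at 0.15, stage II replicate 2), ribosomal proteins (range -0.43 to 0.026, above 0 without stage I replicate 2) and oxidative phosphorylation (-0.026 without stage II replicate 2, range to 0.24). From III to IV it turned numbered zinc finger genes (-0.40 without stage IV replicate 1, range to 0.18). Medians of lists that passed in neither fit turned too, such as p53 response genes from 4 to 6 hpf (0.25) and NuRD genes from 2 to 4 hpf (0.24) with median-of-ratios scaling. In the knockdown znf281b ranged from -0.78 to -0.64, and its call ended without KD replicate 2.

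Of the groups of 3 libraries compared, every same-number pair correlated over 0.1 only for 4 and 6 hpf, which were taken as paired. The 2 pairs of stages I and II each correlated at 0.437, but the deviations of 2 libraries mirror each other, so these pairs are 1 value and were not taken to pair the libraries. Those of 0 and 6 hpf correlated at 0.0856, 0.0921 and 0.144, and those of 0 and 4 hpf, which were not compared, at 0.215, 0.158 and 0.197. Correlations of same-number libraries exceeded 0.1 in 7 of 18 embryo pairs, 2 of 12 oocyte pairs and 1 of 3 knockdown pairs, and 5 of 12, 6 of 8 and 3 of 6 libraries correlated best with their own number. As a hint from the data and not the design, numbers 1, 2 and 3 of 2 hpf correlated at -0.204, -0.199 and -0.103 with their own number of 0 hpf and at 0.319, 0.227 and 0.221 with numbers 2, 3 and 1. With numbers 2, 3 and 1 of 4 hpf they correlated at 0.112, 0.0907 and 0.155, and of 6 hpf at 0.167, 0.121 and 0.122. With a replicate block 0 of the 18 counts moved by over 1.5 times, and the znf281b change stayed at -0.69. If the 2 hpf numbers are shifted, the block mispairs these libraries. It therefore decides nothing on pairing for the counts from 0 to 2 and 2 to 4 hpf. The block brought sox19b in the knockdown past the threshold (adjusted p = 0.0398). It took the calls of nxph1 (0.0892), cd74a from II to III (0.0545), btr02 (0.0558) and bmp2b in the knockdown (0.0533). By camera's preset test it took those of NuRD genes from 0 to 2 hpf (0.0556) and heat shock genes from I to IV (0.0631). For 4 to 6 hpf, a replicate block with only the 2 groups compared, a choice made after seeing the data, gave 2204 rises and 5552 falls and changed no call of a named gene or list.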

Other observations

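The tests of the knockdown developmental sets, of the knockdown counts, of the oocyte markers and of an earlier stage for the p53 genes were chosen only after the result was seen, and the splits for the p53 list and the embryo counts before.

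The genes of this paragraph were chosen after their values were seen. In the knockdown a receptor of apela, aplnrb, was higher (1188 ± 71.1 against 559 ± 23.8 TPM, log2 1.09, limma adjusted p = 0.000527), and its paralogue aplnra lower (-0.90, limma adjusted p = 0.0205). The chemokine gene cxcl12b was higher (1.85) and cxcl12a lower (-0.91). The immediate early genes jun (1.62) and fosab (1.37) and the epidermal regulator gene foxi1 (1.25) were higher. The p53 targets mdm2 (904 ± 114 against 392 ± 78.7 TPM, 1.21) and phlda3 (1.42) were higher too, and both are among the 11 p53 list members already counted as higher.

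For the embryo counts and the knockdown, 10 splits of 6 libraries cannot give a share under 0.05. Every other split also mixes libraries of both groups, so a real difference would itself keep calls and medians there small. The contrast of the real with the other splits, here and for the medians that follow, therefore decides nothing. From 0 to 2 hpf 2 of 10 splits called as many genes as the real 2 (highest other 3). For 2 to 4, 4 to 6 and 0 to 6 hpf it was 1 of 10, with 10727 (highest other 1), 12836 (4) and 14556 (0) genes, and for the knockdown 1 of 10, with 1411 (2). From 4 to 6 hpf, where replicate numbers pair the libraries, the 3 other splits that part all 3 pairs called at most 3 genes, and the 6 that part 1 pair at most 4.

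Part of the genes that rise in development were lower in the knockdown (300 of 890, and 31 higher, for those that rose from 2 to 4 hpf, adjusted p = 0.167 with an estimated correlation), with a median size of 0.69 (1 of 10 splits as large, highest other 0.39, too few for a share under 0.05). The control library pCas13d replicate 3 stood apart, but without it the median was still -0.50, which argues against 1 control library ahead in development as the whole cause. Of 1188 genes called in both comparisons 92.2% moved against the change from 2 to 4 hpf with each comparison's median taken off, which restates the pattern and decides nothing. Whether knockdown embryos were at an earlier point of development cannot be told apart from other causes, because these genes are the ones that show the pattern and the knockdown was sampled only at 4 hpf. With no median taken off, 40 genes were higher in the knockdown and risen from 2 to 4 hpf, 17 lower and fallen, and 133 called in the knockdown were not called from 2 to 4 hpf. A role of znf281b itself stays open and untested, as does a different collection time.

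Of 16 p53 response genes 11 were called higher in the knockdown (adjusted p = 0.354 with an estimated correlation), with a median of 1.08 (1 of 10 splits as large, highest other 0.53, too few for a share under 0.05). The 11 members called had a median change of 0.97 from 2 to 4 hpf, with 7 risen and 1 fallen, and 6 fell from 4 to 6 hpf. Whether knockdown embryos at an earlier point of development could account for them cannot be told apart, because no time between 2 and 4 hpf was sampled. An effect of the guide on RNA other than znf281b also stays open, since no other guide was sampled here. The 11 members called also had higher means in the pCas13d control than in wild-type 4 hpf embryos (6.89-fold at the median, 1.81-fold over all genes), values of separately normalised tables from different sequencers that were not tested and decide nothing.

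From stage I to IV 18 of 24 follicle, 13 of 16 stromal and 14 of 19 blood markers rose (adjusted p = 0.404 for each list with an estimated correlation), with 0 calls in these lists from I to II and 0 stromal calls from III to IV. From stage III to IV the blood median exceeded the stromal median by 1.01 (95% bootstrap interval over genes 0.15 to 1.44, 10000 resamples). Over the 4 pairs of a stage IV and a stage III library the difference was 0.65 to 1.15, and without thy1 it was 0.998. The interval measures spread over genes and not between samples. Stromal markers also held 1329 TPM in 0 hpf embryos, and RNA made outside stromal cells may mute their change. A larger share of all other cell types alike thus cannot be told apart. Isolation that differed by stage may account for part, and cannot be told apart from growth, since stages I and II, isolated alike, had a follicle median change of -0.019, but every later stage differed in both. A change in the follicle cells with growth stays open and untested.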
